A study of Mus musculus with 4 samples.

How the data were processed

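Single-cell RNA-seq was made from bone and bone marrow of mice that carry a tetracycline transactivator (tTA) at 1 allele of Tnfsf11, the gene of the osteoclast-differentiating cytokine RANKL, together with a tTA-driven Cre (LC1) and a Cre-activated tdTomato reporter. Cells in which the Tnfsf11 locus was active while the system was switched on, and their descendants, are tdTomato-positive. Per the labels' protocols, femurs and tibias of both limbs were flushed, minced and digested with collagenase, and live tdTomato-positive cells without CD45.2 and Ter119 were sorted into 10x 3' v3.1 reactions. Animals were pooled before loading, 4 in the control group and 6 in the group with 2 weeks of hindlimb immobilization, all at 10 weeks of age.

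The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 7.0.0 per the file headers and the submitters' processing notes, on the mm10 build per those notes. The annotation release is not given in the sources used here. Feature identifiers and barcodes were deposited as text beside the counts. The feature list has 32286 entries and includes a tdTomato row. Of these identifiers, 32235 matched GENCODE vM21 on GRCm38, the same assembly as mm10, which gave the gene coordinates printed here.

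The 4 deposited libraries are 2 sequencing lanes of each group. In the control group 1617 of 1620 barcodes were shared between the lanes, and in the immobilized group 1747 of 1751. UMIs per shared barcode correlated at r = 0.9999 across cells in the control group and r = 0.9998 in the immobilized group, and the mean chi-square per gene between lanes was 0.534 over 12760 genes in the control group and 0.583 over 12818 genes in the immobilized group, below the value of 1 that independent sampling gives. Entry by entry, the lanes had 79.0% of the lane 1 UMIs in common in the control group and 75.5% in the immobilized group. The lanes differed by less than the sampling noise and were counted as 1 sample per group. Levels and shares within classes were computed in each lane and averaged, so UMI numbers can end in 0.5. The lane sum served to cluster and name cells, to call their sex and to compute their mitochondrial share.

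Barcodes with at least 500 genes and under 10% mitochondrial counts were kept. In the control group 90 barcodes fell short of the gene minimum and 146 reached the mitochondrial limit, and in the immobilized group these were 126 and 300. Scrublet, run per group, called 21 control barcodes (1.30%) and 7 immobilized barcodes (0.401%) as doublets, which were removed. This left 1407 control and 1395 immobilized cells, 87.0% and 79.9% of the shared barcodes.

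Counts were scaled to 10000 per cell and log-transformed, and cells of both groups were clustered together in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, igraph 0.11.9), without batch integration. The 18 clusters were named from markers of 22 cell types fixed before the data were examined. The scoring rule was set after the clusters were seen. A marker counted when its mean was over 2-fold that of all other cells and at least 10% of the cluster had a UMI, and a name needed at least 3 markers and 30% of the list. Clusters of 1 name were pooled into a class. Among the 10 leading genes by fold against cells outside the class, no cluster had more markers of another class than of its own. Against all other cells, clusters 6 and 12 had Kit and cluster 7 had Col2a1 as the only marker there, so values without these clusters were computed too.

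With 1 pool per group no test across animals was possible, and no p-value or count of changed genes is given. Within a class, UMIs were summed over cells, and the ratio of CPM between groups carries an exact conditional binomial 95% interval. Levels carry exact Poisson and shares exact Clopper-Pearson 95% intervals. All of these cover counting error only, not the spread between cells or between animals. The intervals from UMI counts treat UMIs as independent. Log2 ratios use a pseudocount of 0.5 counts. Classes with at least 50 cells in each group were compared, over genes with a mean lane count of at least 50 in at least 1 group; the osteoclast regulators are given whatever their counts. In the 3 classes these were 7971 genes (osteoblast-like), 7475 (Lepr+ CAR stromal-like) and 6717 (osteo-primed stromal-like).

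Except where said below, the named genes followed a rule fixed before the data were examined. In the 2 largest compared classes they are the 12 genes with the highest and the 12 with the lowest log2 ratio, and in the other class the 4 highest and 4 lowest. Each needed a UMI in at least 10% of the class in 1 group, an interval without a ratio of 1, and the same sign in each lane and under median-ratio scaling. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, Y-linked, Gm- and Rik-named genes, Xist and members of the free haematopoietic RNA list were not ranked. The rule added the osteoclast regulators and, for every other list, members with the largest and smallest ratios in the largest class. Members of those lists printed only for a smaller class, unless among the highest and lowest genes above, were outside this rule. Some genes that the rule chose are not reported here.

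For each of 25 gene lists fixed before the data were examined, the median log2 ratio of at least 3 measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. "Outside the random range" means below percentile 2.5 or above percentile 97.5. This describes these libraries and is not a test of the conditions. In simulated counts, 100 genes per class were changed 2-fold, among 7998 genes for osteoblast-like, 7462 for Lepr+ CAR stromal-like and 6652 for osteo-primed stromal-like cells. The intervals excluded a ratio of 1 on the right side for 100%, 99.0% and 98.0% of these changed genes, in that order. Among unchanged genes, 4.44%, 4.42% and 4.67% had an interval without a ratio of 1. This check says nothing on the spread between animals.

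Shares of cells with a UMI were also computed after thinning every cell to 2000 UMIs and leaving out shallower cells. Cells were called female from Xist and male from Y-linked genes. Alternatives fixed beforehand were each lane alone, median-ratio scaling, a stricter filter (1000 genes, 5% mitochondrial counts), a looser filter (200 genes, 20%), Scrublet calls kept, Leiden resolutions 0.5 and 2.0, the mean over cells, thinning, a count minimum of 10 and no count minimum. Alternatives chosen after the data were seen were 1 cluster mix for both groups, female or male cells alone, leaving out clusters 6, 7 and 12, and clustering without 68 genes of the stress, interferon, sex, free-RNA and osteoclast regulator lists. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19.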

Results

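Sorted tdTomato-positive cells of the Tnfsf11 lineage were profiled by droplet single-cell RNA-seq from femurs and tibias of control mice and of mice after 2 weeks of hindlimb immobilization, a model of bone loss from disuse. Each group was 1 pool of animals, 4 control and 6 immobilized. The lanes held 10732720 and 10860328 UMIs in the control group and 9960011 and 10084134 UMIs in the immobilized group. Median depth of the kept cells was 5586.5 UMIs in the control and 5707 in the immobilized pool. There are no replicates, and every interval below covers counting error only. Median mitochondrial share was 3.62% of counts in the control and 5.13% in the immobilized pool before filtering.

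Most sorted cells were of the skeletal stromal lineage. Cells resembling Lepr+ CAR stroma, the Cxcl12-abundant reticular cells of the marrow, made up 39.6% of control cells (557 cells, 95% interval 37.0 to 42.2) and 25.4% of immobilized cells (354 cells, 23.1 to 27.7), a difference of -14.2 percentage points. Osteo-primed stromal-like cells, which express Wif1, Limch1, Tnc and Mmp13, went the other way, from 15.4% (216 cells, 13.5 to 17.3) to 25.5% (356 cells, 23.2 to 27.9). Osteoblast-like cells were 33.3% in each pool (468 and 464 cells). Their markers included Bglap, Col1a1 and Ifitm5 in clusters 3, 4 and 7. Cluster 2, with 55 control and 148 immobilized cells, took the name on Sp7, Ifitm5 and Smpd3 alone, 33.3% of the list. The equal share of the class therefore depends on counting cluster 2 as osteoblast-like. Osteocyte-like cells, with Dmp1, Mepe and Phex and with the heat shock genes Hspa1a, Hspa1b and Hspb1 among the leading genes, numbered 5 in the control pool (0.355%, 0.115 to 0.827) and 42 in the immobilized pool (3.01%, 2.18 to 4.05).

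The shares follow a sort for tdTomato and against CD45.2 and Ter119 and digestion of the bone, and cannot be read as numbers in the tissue. Within the classes the clusters also shifted: cluster 11 held 203 control and 73 immobilized cells of the Lepr+ CAR class, cluster 6 held 118 and 32, and cluster 9 held 157 and 171. Among osteoblast-like cells, cluster 7, led by Atf3 and Ier3, held 170 and 84 cells, and cluster 2, led by Panx3 and Adamts18, held 55 and 148. A pericyte or smooth muscle-like cluster, led by Ndufa4l2 and with Cxcl1, Icam1 and Ier5 among its leading genes, had 54 control and 8 immobilized cells, but its difference of -3.26 points became 2.81 points at Leiden resolution 2.0. The osteoblast-like difference was -5.31 points with the stricter and -4.77 with the looser cell filter. Granulocyte-like cells numbered 37 and 47, B lineage-like cells 21 and 18, erythroid-like cells 11 and 44, endothelial-like cells 9 and 17, and cells of an unnamed cluster led by Cenpf and Top2a 29 and 45.

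**Figure D1:**
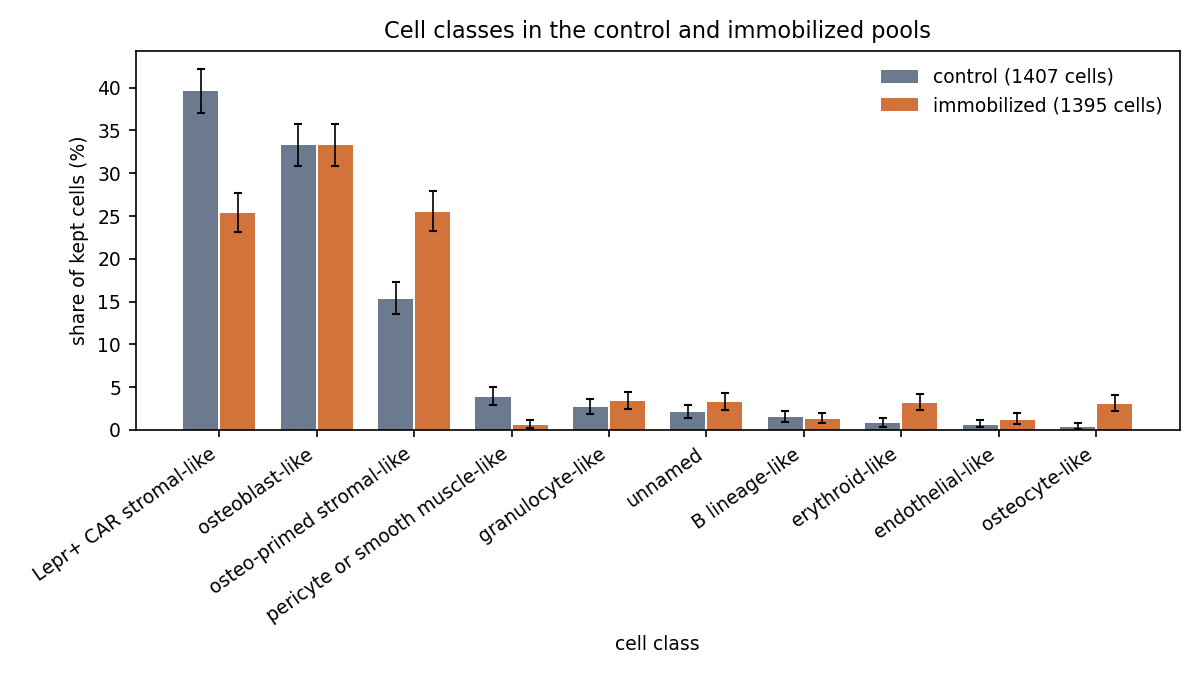
Share of kept cells (%) in each cell class in the control (1407 cells) and immobilized (1395 cells) pools, with exact binomial 95% intervals for counting error as bars. Lepr+ CAR stromal-like cells stand at 39.6% and 25.4%, and osteo-primed stromal-like cells at 15.4% and 25.5%.

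The next comparison asks which cells of this lineage carried Tnfsf11 mRNA and whether its level differed after immobilization. The cells were sorted on a reporter that activity of the Tnfsf11 locus switches on. A change in locus activity could therefore also change which cells were sorted. The levels and shares below cannot separate this from a change within cells. Tnfsf11 (ENSMUSG00000022015, chromosome 14, 78277445 to 78308043, minus strand, protein coding) encodes RANKL, the cytokine required for osteoclast formation. Over all kept cells it stood at 32.4 CPM (counts per 1000000 counts) in the control and 62.8 CPM in the immobilized pool, a ratio of 1.94 (1.69 to 2.23). In Lepr+ CAR stromal-like cells it stood at 92.5 and 221.9 CPM, a log2 ratio of 1.26 (1.03 to 1.50). The share of these cells with a Tnfsf11 UMI was 21.6% in the control and 48.7% in the immobilized pool, and 14.0% and 29.5% after thinning to 2000 UMIs, which left out 49.5 and 13.5 cells.

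In osteo-primed stromal-like cells Tnfsf11 stood at 45.1 and 57.3 CPM (log2 ratio 0.34, -0.09 to 0.78), a difference not detectable at this depth. The share of cells with a UMI was 18.5% and 19.4%. Osteoblast-like cells had 7 control and 14.5 immobilized Tnfsf11 UMIs (1.36 and 3.61 CPM), and osteocyte-like cells had 0 and 0.5 UMIs in 5 and 42 cells. In haematopoietic-like cells, which serve as the background for free RNA, 0.725% of 69 control cells and 0.917% of 109 immobilized cells had a Tnfsf11 UMI, at median depths of 2967.5 and 2209 UMIs. Lepr+ CAR stromal-like cells had median depths of 3976 and 4446.75 UMIs. They held 69.1% of all Tnfsf11 UMIs in the control (63.8 to 74.0) and 73.0% in the immobilized pool (69.0 to 76.5), while osteo-primed stromal-like cells held 21.2% and 22.3%.

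By cluster, Tnfsf11 in cluster 9, the most numerous Lepr+ CAR cluster of the immobilized pool, stood at 55.3 and 289.6 CPM, a ratio of 5.17 (3.68 to 7.96). In cluster 11, the most numerous of the control pool, it stood at 157.1 and 285.0 CPM, a ratio of 1.82 (1.39 to 2.37). Cluster 6 had 66.8 and 66.2 CPM. The pools also differed in the sex of their cells: 47.3% of sexed Lepr+ CAR stromal-like cells were female in the control and 29.8% in the immobilized pool. Tnfsf11 was higher in the immobilized pool within each sex, at 137.2 and 262.0 CPM in female cells (log2 ratio 0.93, 0.58 to 1.29) and 58.1 and 221.6 CPM in male cells (1.92, 1.54 to 2.34).

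**Figure D2:**
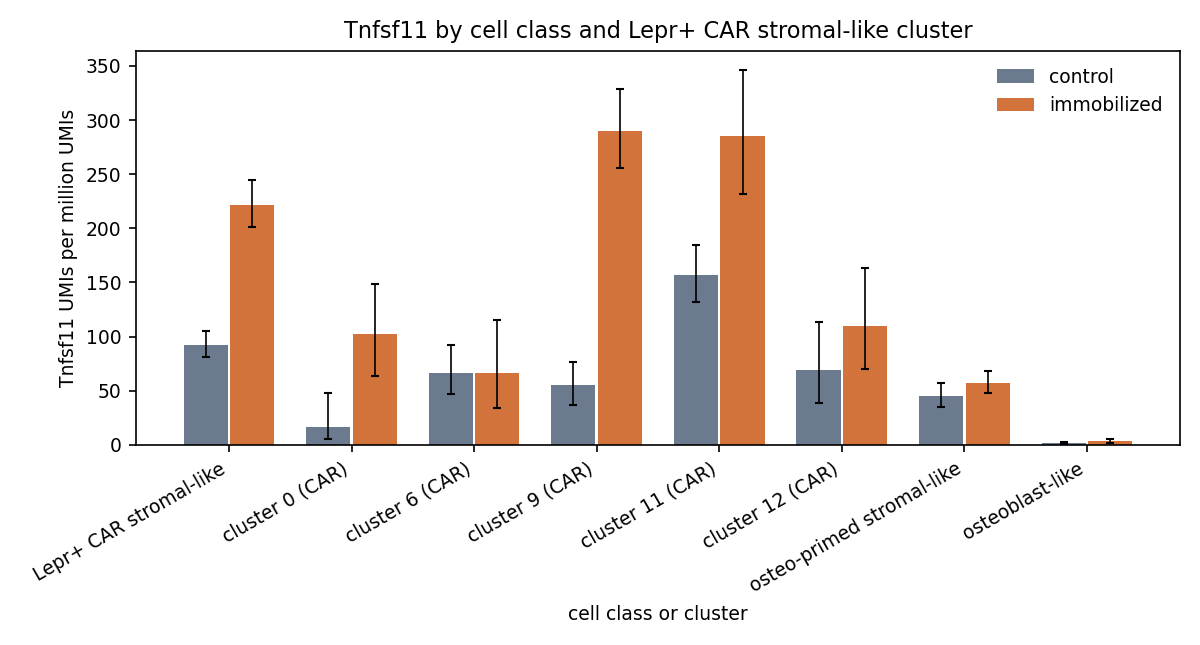
Tnfsf11 level (CPM) in the 3 compared classes and in each Lepr+ CAR stromal-like cluster, control and immobilized, with exact Poisson 95% intervals for counting error as bars. The class stands at 92.5 and 221.9 CPM, cluster 9 at 55.3 and 289.6 CPM, and cluster 6 at 66.8 and 66.2 CPM.

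Among the other regulators of osteoclasts, Tnfrsf11b (ENSMUSG00000063727, chromosome 15, 54250619 to 54278484, minus strand), which encodes the RANKL decoy receptor osteoprotegerin, was lower in osteo-primed stromal-like cells, at 30.9 and 19.3 CPM (log2 ratio -0.68, -1.33 to -0.07) on 48 and 42.5 UMIs, under the count minimum of 50 for compared genes; no alternative was run on this value or on the ratios to it below. The ratio of Tnfsf11 to Tnfrsf11b UMIs in these cells was 1.46 (0.996 to 2.15) in the control and 2.98 (2.10 to 4.36) in the immobilized pool. In Lepr+ CAR stromal-like cells it was 50.8 and 276, on 4.5 and 1.5 Tnfrsf11b UMIs. Csf1, which encodes the macrophage growth factor M-CSF, stood at 402 and 357 CPM in Lepr+ CAR stromal-like cells (log2 ratio -0.17, -0.31 to -0.03), although in female cells alone the log2 ratio was 0.26. Il34, another ligand of the same receptor, had a log2 ratio of -0.37 there, the chemokine Ccl2 -0.76 and Cxcl12 -0.29. Ccl2 stood at 0.05 in male cells and -0.14 at 1 cluster mix, Il34 at -0.14 without clusters 6 and 12, at -0.18 in female and -0.68 in male cells, and Cxcl12 at -0.13 in female and -0.46 in male cells. Over all stromal and skeletal cells, where the mix of classes enters too, Ccl2 had a log2 ratio of -1.39 (-1.995 to -0.84). Il6 had one of -2.04 (-4.64 to -0.41) on 16 and 3 UMIs. Of these control UMIs, 12 were in 0.926% of osteo-primed stromal-like cells, and the interval treats UMIs as independent. In Lepr+ CAR stromal-like cells Il6 had 0.5 and 3 UMIs. Tnfrsf11b (0.47, 0.09 to 0.87) and Csf1 (0.20, 0.11 to 0.29) were higher over all stromal and skeletal cells. This is opposite to the values given above for Tnfrsf11b in osteo-primed and Csf1 in Lepr+ CAR stromal-like cells. Of the 102 and 123.5 Tnfrsf11b UMIs over all these cells, 0 and 38.5 were in osteocyte-like cells (5 and 42 cells). Sema3a, which encodes a semaphorin that restrains osteoclasts, was higher in osteo-primed stromal-like cells (0.37, 0.10 to 0.65) and in osteoblast-like cells (0.72, 0.42 to 1.04, scaled by total counts; 0.36 at 1 cluster mix and 1.05 with the stricter filter). Il6 had 12 UMIs in 0.926% of control and 0 UMIs in immobilized osteo-primed stromal-like cells, and Il11, Tnf and Il1b had at most 3.5 UMIs in any compared class and group. Ptgs2 had 4.5 and 15.5 UMIs in osteo-primed stromal-like cells.

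Lepr+ CAR stromal-like cells of the immobilized pool had higher levels of Vdr, the vitamin D receptor (ENSMUSG00000022479, chromosome 15, 97854425 to 97910630), at 48.2 and 307.1 CPM, a log2 ratio of 2.67 (2.38 to 2.97). Clstn2, which encodes a calsyntenin (ENSMUSG00000032452, chromosome 9, 97444395 to 98033181), stood at 33.4 and 277.9 CPM (3.05, 2.73 to 3.42). The cAMP phosphodiesterase genes Pde3a (2.94) and Pde3b (1.93) and the G protein regulator Rgs2 (1.79) were also among the 12 genes with the highest ratios. So were the lipid genes Fabp4 (2.44, 2.31 to 2.57) and Scd1 (2.02, 1.80 to 2.25), together with Frmd5 (2.88), Kcnh1 (2.39), Shisal1 (2.04), Aoc3 (1.99) and Car3 (1.96). Fabp4 and Scd1 are leading genes of cluster 12, which held 34 control and 33 immobilized cells, and without clusters 6 and 12 the log2 ratio was 0.97 for Fabp4, 2.34 for Scd1 and -0.26 for Car3. Scd1 stood at 1.38 at Leiden resolution 2.0 and 1.26 in female cells. Fabp4 had a log2 ratio of 1.60 in female and 6.72 in male cells, and Tmem86a, among the genes below, one of -0.18 in male cells. Greb1 had the lowest ratio (-2.43, -3.17 to -1.81), and the osteocalcin genes Bglap (-2.13) and Bglap2 (-2.03) and the interferon-induced Isg15 (-1.82) were also low. Sorbs2os, Sh2d4a, Tmem86a, Angptl1, Phf11d, Peg13 and Ifi203 had log2 ratios between -1.79 and -1.52. Among these 11 genes, Sorbs2os stood at -0.99 and Peg13 at -0.74 in female cells, and Greb1 at -1.38, Isg15 at -0.84 and Sh2d4a at -0.39 in male cells. Among those with higher levels, Vdr stood at 2.17 and Kcnh1 at 1.46 in female cells, and the other moves with sex included Pde3a at 4.18 in female and 2.35 in male cells, Frmd5 at 2.39 and 4.01, and Car3 at 0.86 and 3.72. Bglap stood at 692 and 158 CPM here against 28696 and 9071 CPM in osteoblast-like cells, where it was lower too. A Bglap UMI was found in 94.2% of control and 53.5% of immobilized Lepr+ CAR stromal-like cells. Free RNA from osteoblast-like cells was not measured for the osteocalcin genes. Whether such free RNA or expression by Lepr+ CAR stromal-like cells gave these counts was not tested. Reads of Bglap, Bglap2 and Bglap3 can be shared between these near-identical genes, and those of Sorbs2os and Peg13 overlap other genes.

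**Figure D3:**
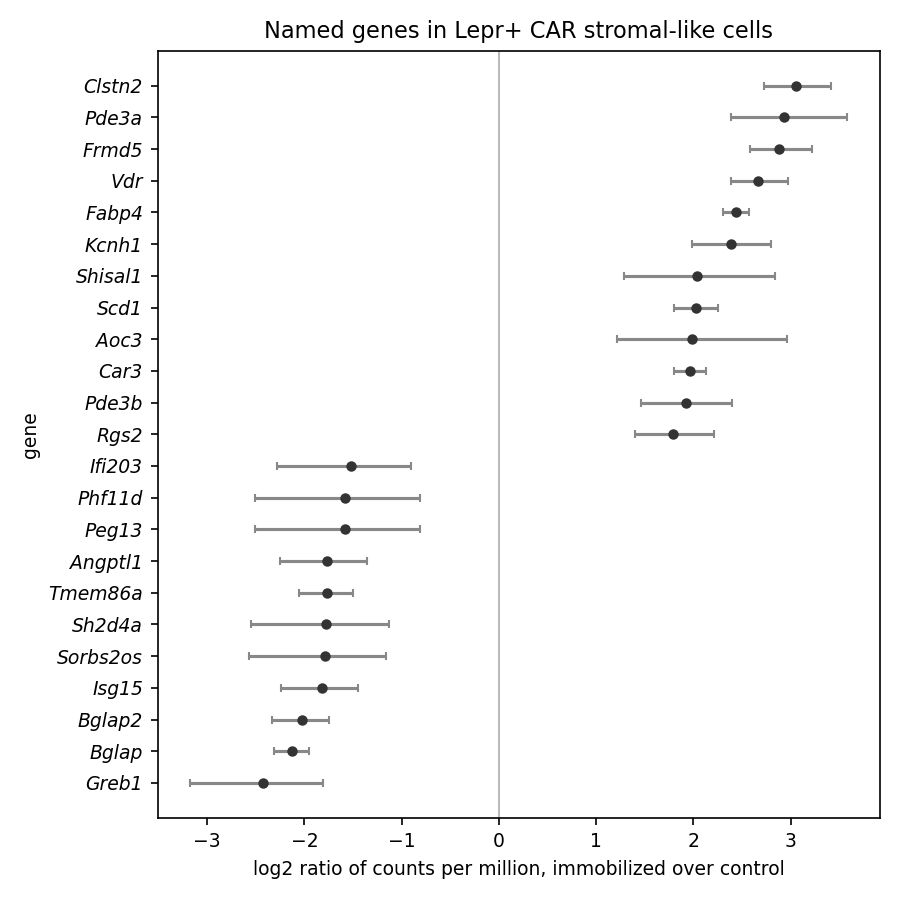
Log2 ratio of CPM, immobilized over control, for the 12 genes with the highest ratio and 11 of the 12 with the lowest in Lepr+ CAR stromal-like cells, with exact conditional 95% intervals for counting error as bars. Clstn2 stands at 3.05, Vdr at 2.67 and Greb1 at -2.43.

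Gene lists in Lepr+ CAR stromal-like cells moved mostly downwards: of 22 lists with a value, 9 had medians below the range of random lists and 3 above it. The osteoblast programme had a median log2 ratio of -0.38, with 12 of 14 measured members lower, among them Ibsp (-0.75), Sparc (-0.54) and Col1a1 (-0.46). Its median was -0.65 with Scrublet calls kept and -0.17 without clusters 6 and 12. How far free osteoblast RNA enters these values, and those of the osteoblast markers below, was not tested. The unfolded protein response stood at -0.37 with 9 of 9 members lower, including Hspa5 (-0.37) and Xbp1 (-0.52). Haematopoietic niche factors stood at -0.17, with 8 of 11 lower, including Bmp4 (-0.75), Il7 (-0.39) and Kitl (-0.28), and Igf1 higher (0.92). The markers of Lepr+ CAR stroma, some of which are niche factors, were lower as a set (median -0.29, 10 of 12 lower), as were the osteoblast markers (-0.54, 7 of 7 lower). The JAK-STAT3 and gp130 list stood at -0.26 (Socs3 -0.44, Osmr 0.78), the TGF-beta and BMP list at -0.20 (Bmp2 -1.40, Tgfbi 1.16) and the osteoclast regulators at -0.29. Proteases and inhibitors were above the range at 0.30, with 9 of 11 higher, among them the collagenase gene Mmp13 (1.09), Adamts1 (0.88) and Mmp2 (0.61). The adipogenic list was inside the range at -0.09, and its members parted, with Adipoq at -0.85 and Plin1 at 1.80, but its median was -0.37 with the stricter filter, -0.36 at Leiden resolution 2.0 and -0.38 without clusters 6 and 12. Within female and male cells the protease median was -0.01 and 0.87, that of the niche factors 0.06 and -0.37, and that of the TGF-beta and BMP list 0.14 and 0.10. The TGF-beta and BMP median was also above 0 without clusters 6 and 12 (0.21), as was the JAK-STAT3 and gp130 median in male cells (0.09).

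In osteo-primed stromal-like cells 8 of 24 lists lay below and 4 above the random range. The adipogenic list had a median of -0.61 with 7 of 7 measured members lower, including Adipoq, an adipokine gene also expressed by Lepr+ CAR cells (90.4 and 7.48 CPM, log2 ratio -3.56, -4.48 to -2.89), and Lpl (-2.42). The markers of Lepr+ CAR stroma as a set were lower in these cells too, with a median of -0.29 and 10 of 12 lower (random range -0.18 to 0.19). Wnt inhibitors stood at -0.85, with Sfrp1 at -1.40, Dkk1 at -0.94, Sfrp4 at -0.75 and Wif1 at 0.03. Niche factors stood at -0.24, with Il7 at -1.45 and Cxcl12 at -0.35. Hypoxia and glycolysis genes stood at -0.27 and the unfolded protein response at -0.29, while mitochondrial encoded genes stood at 0.27 and vitamin D and glucocorticoid response genes at 0.29, with Per1 at 0.54 and Vdr at 0.29. The genes with the highest ratios were Panx3, a pannexin channel gene of bone and cartilage (2.10), Tafa2 (1.97), Cep128 (1.87) and Car1 (1.84), and those with the lowest, besides Adipoq, were Aldh1a2 (-3.01), Trabd2b (-2.91) and the interferon-induced Gbp4 (-2.89). At Leiden resolution 2.0 the log2 ratio of Adipoq was -0.31, that of Cxcl12 was 0.39, and the medians were 0.03 for niche factors, -0.35 for the adipogenic list and -0.43 for Wnt inhibitors. The Wnt inhibitor median was -0.49 with the looser filter and -0.51 with clustering without listed genes, where the adipogenic median was -0.32. The vitamin D and glucocorticoid median was 0.02 with a count minimum of 10. Within male cells Adipoq stood at -0.96, Gbp4 at -1.08, Aldh1a2 at -2.08 and Car1 at 0.75, and the medians were -0.16 for the adipogenic list, -0.35 for vitamin D and glucocorticoid response, 0.22 for niche factors and 0.02 for the unfolded protein response; in female cells the adipogenic median was -1.15 and the vitamin D and glucocorticoid median 0.59.

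In osteoblast-like cells the median log2 ratio over genes with a mean lane count of at least 50 in each group was 0.21 by total counts. Values for this class are given relative to that shift from here on, unless said to be by total counts. The osteocalcin genes Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464) and Bglap2 were lower, at -1.88 and -1.80, as were Bglap3 (-2.13) and the cartilage collagen gene Col2a1 (-2.17). The osteoblast programme as a whole was inside the random range, since its members parted: the matrix gene Spp1 stood at 1.33 and the transcription factor gene Runx2 at 0.58, against -0.40 for Col1a1 and -0.57 for Sparc. Wnt targets were above the range with a median of 0.85, with Notum and the cyclin gene Ccnd1 at 1.29 and 1.28, Tcf7 at 0.41 and Nkd2 at -0.22. By total counts this median was 1.06, and it was 0.62 with a count minimum of 10, 0.52 at 1 cluster mix, 1.70 with the stricter filter and, over members with at least 10 counts, 0.43 in male cells, inside the random range. The markers of osteo-primed stroma as a set were higher in osteoblast-like cells, with a median of 1.09 by total counts and 6 of 7 higher (random range -0.31 to 0.46). All 7 measured vitamin D and glucocorticoid response genes were higher (median 0.70), including Zbtb16 (2.01), Per1 (0.97), Fkbp5 (0.73) and Vdr (0.46).

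Other genes of this class with the highest ratios were Hist1h1b (2.66), Btbd8 (2.16), Cpa6 (2.06), Btla (1.86), the Wnt agonist receptor gene Lgr6 (1.83), Panx3 (1.62), Glis3 (1.57), Enox1 (1.55), Anxa1 (1.48), Ino80dos (1.45), Zfpm2 (1.43) and Limch1 (1.41). Those with the lowest included the heat shock genes Hspa1a (-2.79), Hspa1b (-2.59) and Hsph1 (-1.67), the interferon-induced Irgm2 (-2.19) and Bst2 (-1.71), and BC055402 (-1.80), AU021092 (-1.72) and Homer2 (-1.65). Mitochondrial encoded genes stood at 0.18, and the TGF-beta and BMP list at -0.44 and hypoxia and glycolysis at -0.33 were below the range. By total counts the TGF-beta and BMP median of -0.23 became 0.02 at 1 cluster mix and 0.23 in male cells, and the hypoxia median of -0.11 became 0.04 without cluster 7. With both groups set to 1 cluster mix, and scaled by total counts, Ccnd1 changed from 1.50 to 0.49 and Bglap from -1.66 to -1.43. In male cells alone, 29 control and 97 immobilized, the log2 ratio by total counts was -0.43 for Bglap, -0.73 for Hspa1a, 0.33 for Cpa6, -0.50 for Zfpm2, -1.11 for Limch1, 3.32 for Col2a1, 1.92 for BC055402 and -0.72 for AU021092. In these male cells it was also 0.23 for Anxa1, 0.54 for Glis3, 0.73 for Enox1, 1.04 for Btbd8, 1.30 for Btla, 1.16 for Ino80dos, -0.65 for Irgm2, -1.05 for Bst2, -0.49 for Bglap2 and -0.90 for Bglap3.

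The interferon response, immediate early and heat shock lists were below the random range in all 3 classes. All measured interferon genes were lower, 12 of 12 in Lepr+ CAR stromal-like cells (median -1.13), 6 of 6 in osteo-primed stromal-like cells (-0.99) and 6 of 6 in osteoblast-like cells (-1.21), with medians below all 10000 random lists. In Lepr+ CAR stromal-like cells Ifit3 stood at -2.17 and Bst2 at -1.47. Immediate early genes, many of which respond to cell isolation, had medians of -0.61, -0.33 and -0.74, with Fos at -0.40, -0.52 and -0.74. Heat shock genes had medians of -0.35, -0.71 and -1.32. With 1 cluster mix for both groups the immediate early median in osteoblast-like cells was 0.14 by total counts, and it was 0.13 in male cells alone and -0.11 without cluster 7; the heat shock median of -1.10 by total counts was -0.64, -0.39 and -0.65 in these settings. In osteo-primed stromal-like cells the immediate early median was 0.04 in female and -0.69 in male cells, and -0.58 at Leiden resolution 2.0, and the heat shock median -0.06 in male cells. In Lepr+ CAR stromal-like cells the heat shock median was -0.18 in female and 0.02 in male cells (-0.74 and -0.40 with a count minimum of 10), and the interferon median in male cells was -0.48. In osteo-primed stromal-like cells the interferon median with a count minimum of 10 was -1.47 in female cells and -0.20 in male cells, where it was inside the random range with 3 genes higher and 5 lower. The immediate early median in Lepr+ CAR stromal-like cells lay between -1.34 and -1.17 with the looser filter, with Scrublet calls kept, at Leiden resolutions 0.5 and 2.0 and with clustering without listed genes, and the heat shock median lay between -0.90 and -0.81 in these settings apart from Leiden resolution 0.5. Within female Lepr+ CAR stromal-like cells the immediate early median was -1.23, and within male ones -0.40.

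Signs of the sample makeup moved alongside these lists. The free haematopoietic RNA list, whose genes these cells should lack, had medians of 1.31 in Lepr+ CAR stromal-like cells, 0.93 in osteo-primed stromal-like cells and 0.90 in osteoblast-like cells. Y-linked genes had medians of 0.49, 0.47 and 1.79. Of the sexed osteoblast-like cells, 93.5% were female in the control and 77.6% in the immobilized pool, and of the osteo-primed stromal-like cells 67.7% and 55.9%.

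The remaining lists were inside the random range under the main settings. In Lepr+ CAR stromal-like cells these were Wnt inhibitors, fibrillar matrix and crosslinking, NF-kB and inflammatory, mechanical and YAP targets, PTH and cAMP response, vitamin D and glucocorticoid response, hypoxia and glycolysis, mitochondrial encoded, and senescence and cell cycle arrest, with medians from -0.23 to 0.19. The NF-kB and inflammatory median of -0.06 in these cells was -0.36 with the looser filter, -0.32 with Scrublet calls kept, -0.35 and -0.50 at Leiden resolutions 0.5 and 2.0 and -0.34 with clustering without listed genes. In female cells the Lepr+ CAR medians were 0.78 for vitamin D and glucocorticoid response, -0.60 for senescence, -0.59 for Wnt inhibitors and -0.21 for PTH and cAMP; in male cells they were -0.44 for vitamin D and glucocorticoid response, 0.26 for senescence and 0.43 for hypoxia. The PTH and cAMP median was -0.11 with Scrublet calls kept, and the fibrillar matrix median -0.14 without clusters 6 and 12. Wnt targets, the osteocyte programme and proliferation had under 3 measured members there, and proliferation also in the other classes. In osteo-primed stromal-like cells the lists inside the range were osteoclast regulators, Wnt targets, osteoblast and osteocyte programmes, fibrillar matrix, proteases, NF-kB, JAK-STAT3, mechanical and YAP targets, TGF-beta and BMP, PTH and cAMP, and senescence, with medians from -0.19 to 0.22. Among these, female cells had -0.44 for the osteocyte programme and -0.54 for NF-kB, male cells had 0.10 for NF-kB, 0.31 for proteases and -0.22 for the osteoblast programme, a count minimum of 10 gave -0.13 for osteoclast regulators and -0.20 for JAK-STAT3, and Wnt targets stood at 0.37 with Scrublet calls kept and 0.43 with clustering without listed genes. In osteoblast-like cells they were osteoclast regulators, Wnt inhibitors, osteoblast, osteocyte and adipogenic programmes, niche factors, fibrillar matrix, proteases, NF-kB, JAK-STAT3, mechanical and YAP targets, PTH and cAMP, senescence and the unfolded protein response, with medians from -0.40 to 0.08. By total counts, the stricter filter gave 0.85 for osteoclast regulators, 0.94 for Wnt inhibitors and -0.42 for the adipogenic list, 1 cluster mix gave -0.39 for osteoclast regulators and 0.46 for PTH and cAMP, and male cells had -0.16 for the osteocyte programme.

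**Figure D4:**
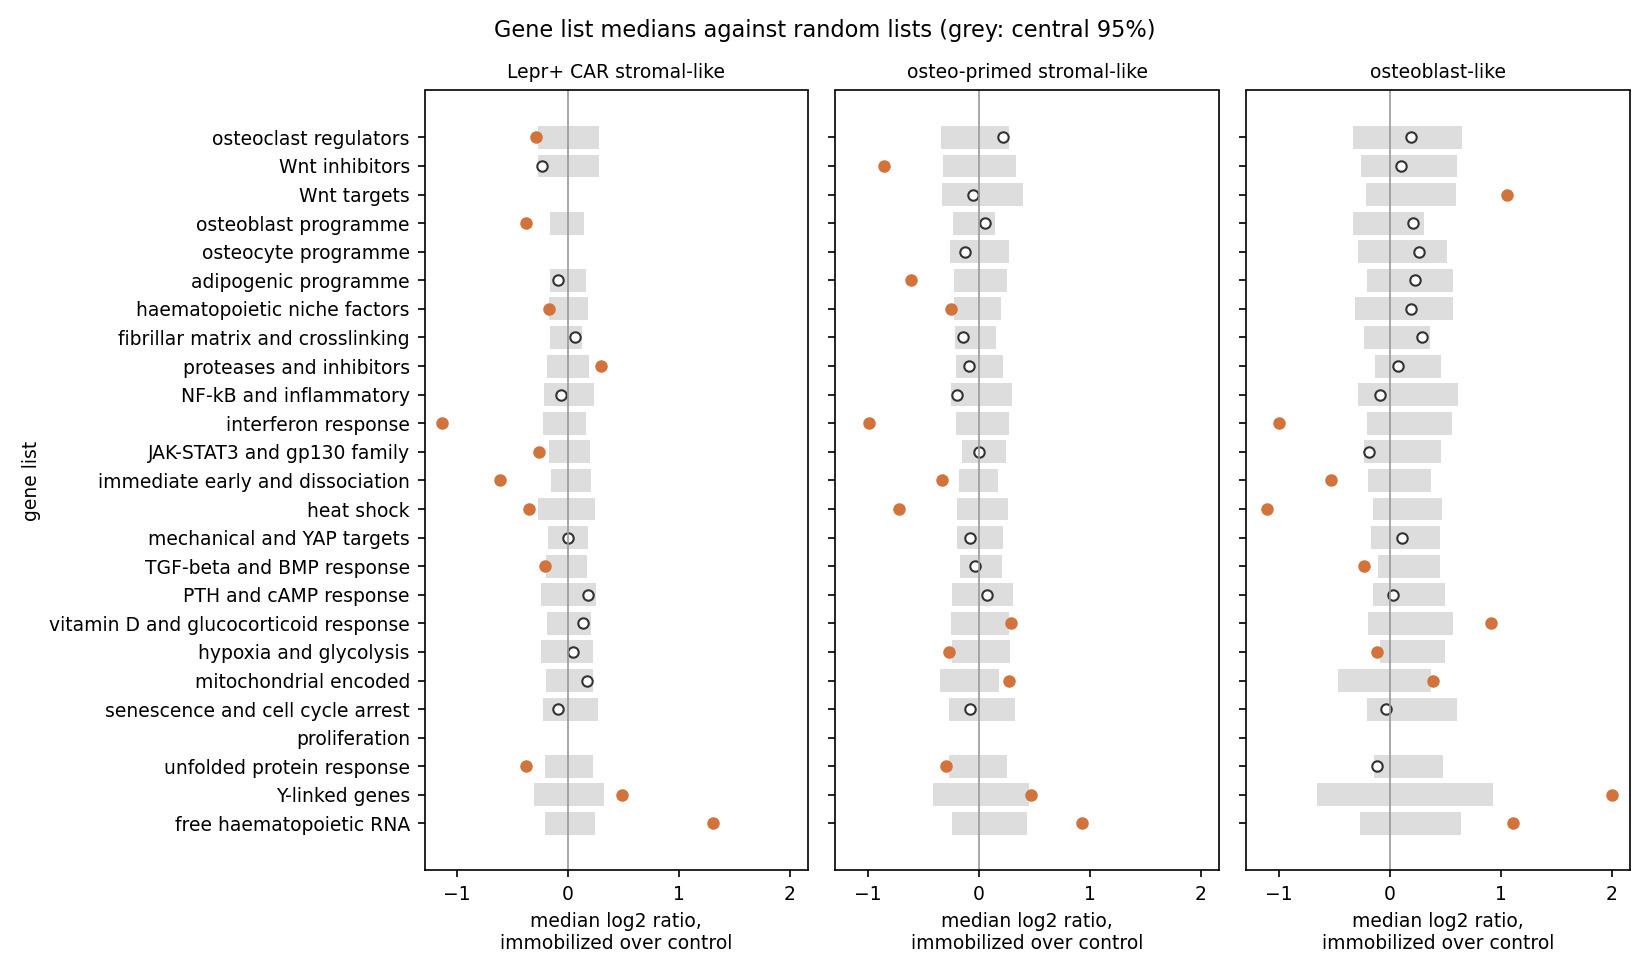
Median log2 ratio by total counts, immobilized over control, of each gene list in the 3 compared classes; grey bars span the central 95% of 10000 random lists, filled points lie outside it and open points inside. The interferon list stands at -1.13 in Lepr+ CAR stromal-like cells and the Wnt targets at 1.06 in osteoblast-like cells.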

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

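The tests of the cluster mix and of free RNA for Tnfsf11, of sex for the interferon genes in 2 classes and in female osteo-primed stromal-like cells and of sex for the Wnt targets in female cells were chosen after the results were seen. Genes among those named in the report that stood on opposite sides of 1 in different classes, with both intervals excluding 1, are given first by total counts; the differences between classes were not tested. Car3 had a log2 ratio of 1.96 in Lepr+ CAR stromal-like and -0.41 in osteoblast-like cells, but the opposite direction was absent where the Lepr+ CAR value was itself below 0: -0.323 with the stricter filter, -0.322 at Leiden resolution 2.0 and -0.262 without clusters 6 and 12. Glis3 stood at 1.79 in osteoblast-like and -0.41 in osteo-primed stromal-like cells, with 0.54 in male osteoblast-like cells. Sorbs2os stood at 0.38 in osteoblast-like and -1.79 in Lepr+ CAR stromal-like cells, and Zfpm2 at 1.65 and -0.46, although in male osteoblast-like cells Zfpm2 stood at -0.50. Haematopoietic-like cells, which a sort against CD45.2 and Ter119 should remove, made up 4.90% of control cells (69 cells, 3.84 to 6.17) and 7.81% of immobilized cells (109 cells, 6.46 to 9.35), above the limit that a count of 0 allows.

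Tnfsf11 was higher in Lepr+ CAR stromal-like cells of the immobilized pool (log2 ratio 1.26). The tables argue against a shift between clusters as the whole account, with a log2 ratio of 1.375 (1.14 to 1.62) for both groups at 1 cluster mix, and against the sex of the cells, with 0.934 as the smaller of the ratios within a sex. Free RNA in the droplets would reach osteoblast-like cells too, but the upper bound of Tnfsf11 there was 5.85 CPM in the immobilized pool against a rise of 129.4 CPM. A difference between the pools other than immobilization cannot be told apart from it, because there is 1 pool per group. Whether the sort on a reporter that the Tnfsf11 locus switches on let different cells into each pool was not tested. A response of Lepr+ CAR stromal cells to disuse may be one account and stays a hypothesis.

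Immediate early, heat shock and interferon genes were lower in the immobilized pool by the class medians of the 3 compared classes, although the immediate early median was above 0 in osteoblast-like cells at 1 cluster mix (0.135) and in male cells (0.126) and in female osteo-primed stromal-like cells (0.037, but -0.054 with a count minimum of 10), and the heat shock median in male Lepr+ CAR stromal-like cells (0.017, but -0.403 with that minimum). If stress during cell preparation differed between the pools, haematopoietic-like cells of the same suspensions could carry the difference too. In granulocyte-like cells (37 and 47 cells) the immediate early median was -0.832, below the random range (lower bound -0.26). This was the outcome set beforehand for that account. The median was 2.39, above the range, in erythroid-like cells (11 and 44 cells). It was inside the range in B lineage-like (-0.14) and endothelial-like cells (-0.17). The heat shock median was -0.88 in granulocyte-like cells, below its range (lower bound -0.58). It was inside the range in erythroid-like (-0.88), B lineage-like (-0.45) and endothelial-like cells (-0.91). On so few cells, the preparation account cannot be told apart from others. For the interferon genes, with a count minimum of 10, a sex mix as the whole account is argued against in Lepr+ CAR stromal-like and osteoblast-like cells by a median of at most -0.593 within each sex (in male Lepr+ CAR cells -0.481 at the main minimum) and in osteo-primed stromal-like cells by -1.466 in female cells (random range -0.29 to 0.37), while in male ones it was -0.201, inside the random range. The outcome set beforehand against a sex mix was an interferon median below the range within each sex. Male osteo-primed stromal-like cells did not meet it. In granulocyte-like cells the interferon median was -2.36 over 6 genes, 5 lower and 1 higher, below the random range (-1.07 to 1.88). This goes against a difference restricted to the skeletal lineage. The granulocyte value rests on 37 and 47 cells at median depths of 3286 and 1442.5 UMIs, with a count minimum of 10. On still fewer cells, the interferon median was also below its range in B lineage-like cells (-1.71 over 3 genes, lower bound -1.59, 21 and 18 cells). In endothelial-like cells it was -1.19 over 5 genes, 4 lower and 1 higher (lower bound -1.05, 9 and 17 cells). Erythroid-like cells had no measured interferon gene. A lower interferon state of the whole immobilized pool of animals, from immobilization or from housing or infection history, remains untested.

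Wnt target genes were higher and osteocalcin genes lower in osteoblast-like cells of the immobilized pool. With both groups at 1 cluster mix the Wnt median, by total counts, changed from 1.06 to 0.517, just above the random range (upper bound 0.464), which argues against the cluster mix as the whole account while a part of the difference went with it. These clusters were themselves built with Ccnd1 and Panx3 among their leading genes, and the list had 4 measured members. Within female cells the Wnt median was 0.885 (random range -0.25 to 0.65). This argues against the sex mix as the whole account of the Wnt targets. In male cells, 29 of them in the control, the Wnt median was 0.429, inside the random range. The outcome set beforehand against a sex mix, a Wnt median above the range within each sex, was thus not met. The osteocalcin genes had no such test. By total counts, Bglap stood at -1.81 in female and -0.43 in male cells, and Bglap2 at -1.72 and -0.49. Less mature osteoblasts in the immobilized pool may be one account, which no test here separates from a difference in how bone was digested.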

How the results depend on the processing

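Cluster mix, cells of 1 sex, leaving out clusters 6, 7 and 12 and clustering without listed genes were chosen after the data were seen. No paired analysis was possible because the replicate numbers are lanes of 1 library per group and no test was run; with either lane left out, no value reversed or left its interval. Values here are by total counts. The Tnfsf11 log2 ratio in Lepr+ CAR stromal-like cells stayed above 0 in all 14 alternatives run on it, from 0.93 to 1.92, and the interferon medians stayed below 0 in all that gave one. Over all alternatives, those with a lane left out included, 100 values of osteoclast regulators stayed within their interval, 35 moved and 5 reversed; for named genes these were 632, 131 and 7, and for gene lists 958, 81 and 18. Depth limits Tnfrsf11b in Lepr+ CAR stromal-like cells (4.5 and 1.5 UMIs) and Tnfsf11 in osteoblast-like cells (7 and 14.5 UMIs). Apart from fewer or shallower cells where named, the cause was not tested for any change below.

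The difference in share of cells (immobilized minus control, percentage points) for osteoblast-like cells was -5.31 with the stricter and -4.77 with the looser filter. For osteo-primed stromal-like cells it was 14.2 with the stricter filter, and for Lepr+ CAR stromal-like cells -18.0 with Scrublet calls kept, -19.6 at resolution 2.0 and -18.0 without listed genes. For pericyte or smooth muscle-like cells it was 0 with the stricter and 0 with the looser filter, since no cluster took the name, 0.233 with Scrublet calls kept, -0.565 at resolution 0.5, 2.81 at resolution 2.0 and 0.152 without listed genes. The control share of Tnfsf11 UMIs in Lepr+ CAR stromal-like cells, 69.1%, was 74.8% with the looser filter, 74.8% with Scrublet calls kept, 74.4% and 75.6% at resolutions 0.5 and 2.0, and 74.9% without listed genes.

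With the stricter filter, Car3 in Lepr+ CAR stromal-like cells had a log2 ratio of -0.323 and, in osteo-primed stromal-like cells, Cxcl12 0.072, niche factors 0.0076 and 7 lists outside the random range instead of 12. At resolution 2.0 these were -0.322 for Car3, 0.39 for Cxcl12 and 0.035 for niche factors, and without listed genes Cxcl12 stood at 0.11. Over all stromal and skeletal cells the Tnfsf11 log2 ratio of 0.98 was 0.68 as a mean over cells and 0.55 in female cells. With no count minimum the median absolute log2 ratio was 0.404 in Lepr+ CAR stromal-like and 0.506 in osteo-primed stromal-like cells, since rare genes entered. After thinning, the share of cells with a Tnfsf11 UMI was 0.434% and 1.00% in control and immobilized osteoblast-like cells, 14.0% and 29.5% in Lepr+ CAR stromal-like and 8.49% and 8.74% in osteo-primed stromal-like cells, by fewer UMIs per cell. In osteoblast-like cells, 1 cluster mix gave an immediate early median of 0.135 and a TGF-beta and BMP median of 0.016. Without cluster 7 the hypoxia median was 0.038 with 6 lists outside the range instead of 10; without clusters 6 and 12, Car3 stood at -0.262 and the TGF-beta and BMP median in Lepr+ CAR stromal-like cells at 0.207.

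In female cells alone, Lepr+ CAR stromal-like values were 0.93 for Tnfsf11, 0.26 for Csf1, 0.063 for niche factors, -0.011 for proteases and 0.14 for TGF-beta and BMP, and the immediate early median in osteo-primed stromal-like cells was 0.037. In male cells alone, Lepr+ CAR stromal-like values were 1.92 for Tnfsf11, 0.050 for Ccl2, 0.091 for JAK-STAT3 and gp130, 0.017 for heat shock and 0.097 for TGF-beta and BMP. Osteoblast-like values in male cells, from 29 control cells, were -0.57 for Tnfsf11, -0.50 for Zfpm2, -1.11 for Limch1, 3.32 for Col2a1, 1.92 for BC055402, 0.126 for immediate early and 0.234 for TGF-beta and BMP, with 1 list outside the range. Osteo-primed stromal-like values in male cells were 0.218 for niche factors, -0.352 for vitamin D and glucocorticoid response and 0.018 for the unfolded protein response, with 7 lists outside the range.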

Other observations

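Osteocyte-like cells of the immobilized pool carried Tnfrsf11b, the osteoprotegerin gene, at 394 CPM (38.5 UMIs in 42 cells), and the 5 control cells of this class had 0 UMIs of it. The fibrillar matrix list as a whole was inside the random range in each compared class, with medians by total counts of 0.30 in osteoblast-like cells (9 genes higher, 5 lower), 0.06 in Lepr+ CAR stromal-like cells (8 and 8) and -0.14 in osteo-primed stromal-like cells (6 and 9). Single matrix genes are given here as values, chosen after these were seen, and no difference between classes was tested. In osteoblast-like cells, relative to the class shift, the collagen VI genes Col6a1 (0.89), Col6a2 (0.79) and Col6a3 (0.70), Col3a1 (1.12) and the tenascin gene Tnc (1.14) were higher and the crosslinking gene Loxl2 (-0.96) lower. In osteo-primed stromal-like cells Col3a1 (-1.20), Col6a1 (-0.65) and Col6a2 (-0.63) were lower. In Lepr+ CAR stromal-like cells Fn1 (1.25), Fbn1 (1.09) and Col3a1 (0.53) were higher.

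The reporter transcript itself was seen in 45.8% of control and 43.5% of immobilized osteoblast-like cells, 36.6% and 40.7% of osteo-primed stromal-like cells and 19.8% and 26.8% of Lepr+ CAR stromal-like cells, against 1.45% and 1.38% of haematopoietic-like cells. Osteoblast-like cells were deeper, at median UMI counts of 9735 and 8198.5.

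The sexes of the cells were spread unevenly over the classes within each pool. In the control pool 93.5% of sexed osteoblast-like cells but 47.3% of Lepr+ CAR stromal-like cells were female, and in the immobilized pool these were 77.6% and 29.8%. In control Lepr+ CAR stromal-like cells Tnfsf11 stood at 137.2 CPM in female and 58.1 CPM in male cells, and in immobilized ones at 262.0 and 221.6 CPM. The number of animals of each sex in each pool is not given in the sources used here.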
